A study of Homo sapiens with 9 samples.

How the data were processed

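The libraries were made from total RNA of DMS273 cells grown in RPMI 1640 with 10% fetal bovine serum. Per the labels' protocols, 400 ng of RNA was depleted of rRNA and turned into strand-specific libraries with dUTP marking and 12 PCR cycles. Reads were aligned with HISAT2 to hg38, per the submitters' processing notes, which name no versions. The counting program, its annotation and its strand setting are not given in the sources used here. The deposited values are whole-number counts per gene with 1 column per library, and no normalization was applied by the authors as far as the values show. The table lists 67140 genes, of which 31038 have no count in any library. In its library columns 362598 cells are missing and no cell holds a 0, so the missing cells were read as 0. Also left out were 1 row that numbers the columns and 1 unlabelled column outside the libraries, which holds 0 in all 67140 cells. Gene IDs were matched to GENCODE release 29 for type and GRCh38 coordinates, GC content and length, with 58503 IDs matched, which hold 99.96% of all counts. The files pair IDs with symbols, and the symbols used are theirs.

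Groups follow the labels: control (scrambled guide), ATG7 KO and ATG7/SQSTM1 KO, with 3 libraries each. The labels do not say whether the libraries of a group come from separate cultures. If they do not, p-values measure only the spread between these samples, which may be technical. Library totals ran from 28675576 to 34222098 counts, with 26075 to 27439 genes detected, and the 10 most abundant genes took 4.83% to 6.32% of a library. The share of mitochondrially encoded counts is known closely at this depth, for example 3.87% with a binomial 95% confidence interval of 3.863% to 3.877% in ATG7 KO replicate 1. Between libraries of a group the counts differed by more than sampling alone gives, with chi-square per degree of freedom from 4.47 to 7.03 over genes with at least 20 counts in a pair.

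Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr by group (minimum count 10), which left 18847, and libraries were scaled with TMM (factors 0.977 to 1.01). A robust quasi-likelihood fit took all 9 libraries with group means and 6 residual degrees of freedom. The common biological coefficient of variation was 6.39%. The comparisons were ATG7 KO against control, ATG7/SQSTM1 KO against control, and ATG7/SQSTM1 KO against ATG7 KO, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Genes changed in ATG7 KO and changed in the opposite direction between both knockouts were counted and set beside 20 simulated draws. The fit, the comparisons, the lists and the rule for named genes were fixed before the data were examined.

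Of 32 gene lists written from textbook knowledge, 31 had at least 5 tested members and were tested with camera in limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), adjusted over the lists of a comparison, and again with an estimated correlation. Members past the edgeR threshold were counted over all tested genes and again adjusted over the list alone, and the report gives the second count where it differs. The lists overlap: COL1A1 is in the fibroblast and epithelial-mesenchymal lists, VIM and TGFBI in the non-neuroendocrine and epithelial-mesenchymal lists, AXL and MYOF in the non-neuroendocrine and YAP/TAZ lists, and DLL3 in the neuroendocrine and Notch lists. BAX and BBC3 are in the p53 and BCL2 lists, ABCC1, ABCC2 and ABCC3 in the NRF2 and drug efflux lists, MYC in the ribosome biogenesis and immediate early lists, and ATF3 in the ATF4 and immediate early lists. Genes are named by rule: ATG7 and SQSTM1, then the 8 largest rises and 8 largest falls among changed genes of at least 5 CPM in the higher group whose 3 libraries do not overlap between groups (noncoding clone names and pseudogenes skipped), then up to 4 members of each list with the smallest p. PDGFRA (ATG7 KO against control) and COL6A3 (ATG7/SQSTM1 KO against control) fall outside that rule in those comparisons and were chosen after their values were seen. A test on the fibroblast markers that were not called was dropped, since that choice of markers fixed its outcome, and a test on the spread of the neuroendocrine markers took its place after the data were seen. Some genes the rule names are not reported here.

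The scripts were tested on simulated counts for the real genes, with 200 genes changed by known folds, 50 per fold. For ATG7 KO against control (18530 genes) the fit recovered 19, 27, 35 and 42 of 50 genes changed 1.25, 1.5, 2 and 4-fold, with 16 false calls. For ATG7/SQSTM1 KO against control (18461 genes) it recovered 24, 31, 34 and 46 with 7 false calls, and for ATG7/SQSTM1 KO against ATG7 KO (18497 genes) 25, 32, 41 and 44 with 9 false calls. Every recovered gene had the right sign.

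Alternatives were relative log expression size factors, library totals alone, no low-count filter, a minimum mean of 1 CPM, DESeq2 1.42.0, a fit of the 6 libraries compared, the replicate number as a block, a 1.5-fold null, and leaving out each library. For the list tests, relative log expression size factors and leaving out each library were added after the data were seen. Tables and figures were made with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.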

Results

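RNA from DMS273, a human small cell lung cancer line, was sequenced after rRNA depletion in 9 libraries. Per the labels, the cells carried either a scrambled guide (control), a CRISPRv2 knockout of ATG7 (ATG7 KO), or knockouts of both ATG7 and SQSTM1 (ATG7/SQSTM1 KO), with 3 libraries in each group. ATG7 encodes the E1-like enzyme that starts the conjugation of ATG12 and of the LC3 family during autophagosome formation. SQSTM1 encodes p62, a receptor that binds ubiquitylated cargo and is itself degraded by autophagy. The series is about mechanisms of drug resistance in this cancer, and no drug treatment is part of the libraries used here. The control libraries held 32538275, 28675576 and 30903274 counts. The ATG7 KO libraries held 29791807, 30552603 and 31895461, and the ATG7/SQSTM1 KO libraries 34222098, 28850265 and 31133819. Counts from mitochondrially encoded genes made up 3.87% to 6.04% of a library. On a multidimensional scaling plot of the libraries, dimension 1 (48.6% of the variance) placed the ATG7 KO libraries apart from the other 6, and dimension 2 (18.9%) parted control from ATG7/SQSTM1 KO. Levels below are TMM-scaled CPM, given as mean ± SD over the 3 libraries of a group. Log2 changes carry their standard error (SE), and adjusted p-values for single genes are from edgeR.

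The targeted genes were read first. ATG7 (ENSG00000197548; GRCh38 chromosome 3, 11272309 to 11557665, plus strand, protein coding) stood at 28.1, 26.4 and 26.8 CPM in the control libraries, at 12.0, 9.99 and 13.0 CPM in the ATG7 KO libraries, and at 11.2, 10.4 and 10.2 CPM in the ATG7/SQSTM1 KO libraries. It was thus lower in both knockouts than in control (log2 change −1.22 in ATG7 KO, edgeR adjusted p = 2.69e-11, and −1.35 in ATG7/SQSTM1 KO, edgeR adjusted p = 2.46e-11). SQSTM1 (chromosome 5, 179806398 to 179838078, plus strand, protein coding) stood at 380.2, 375 and 373 CPM in control and at 388, 396 and 389 CPM in ATG7 KO. In the ATG7/SQSTM1 KO libraries it stood at 55.3, 48.8 and 51.6 CPM, a log2 change of −2.86 against control (edgeR adjusted p = 1.37e-22). No library went against its label. The sites of the guides within the genes are not given in the sources used here, and transcripts of an edited gene can remain detectable. Between ATG7 KO and control, SQSTM1 differed by 0.05 on the log2 scale (edgeR adjusted p = 0.156), and a DESeq2 test put the same difference at 0.07 with an adjusted p of 0.0368. Between both knockouts, ATG7 differed by −0.14 (edgeR adjusted p = 0.176). Without ATG7 KO replicate 2 that difference was −0.24 (edgeR adjusted p = 0.0127).

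**Figure D1:**
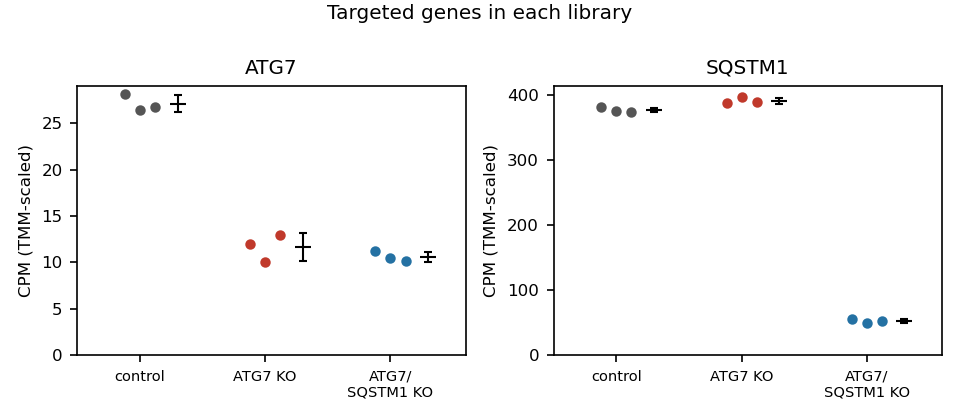
ATG7 and SQSTM1 in CPM (vertical axes) in each of the 9 libraries; points are libraries and the bars beside them are the mean ± SD of the 3 libraries of a group. ATG7 lay at 9.99 to 13.0 CPM in both knockouts against 26.4 to 28.1 CPM in control, and SQSTM1 fell to 48.8 to 55.3 CPM in the ATG7/SQSTM1 KO libraries alone.

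The first comparison, ATG7 KO against control, asks which transcripts differ in DMS273 cells after loss of ATG7. In ATG7 KO cells every tested interferon-stimulated gene was higher, MHC class I and antigen presentation genes were higher, and neuroendocrine genes were lower while non-neuroendocrine genes were higher. IFITM3, which restricts the entry of enveloped viruses, rose from 78.3 ± 1.9 to 430.2 ± 13 CPM. NEUROD1, a transcription factor of neuroendocrine small cell lung cancer, fell from 194 ± 3.9 to 73.3 ± 0.93 CPM, and YAP1, a coactivator mostly absent from neuroendocrine tumours of this kind, rose from 31.8 ± 1.6 to 99.4 ± 3.3 CPM. Across 18847 tested genes, edgeR's quasi-likelihood test called 10688 changed (56.7%), 5348 higher and 5340 lower in ATG7 KO. Of these, 795 were at least 2-fold higher and 1561 at least 2-fold lower. Among the largest rises were STEAP4, a metalloreductase (0.494 ± 0.12 to 19.2 ± 0.76 CPM, 38.4-fold), the water channel AQP1 (19.5-fold), the acute phase gene SAA1 (12.7-fold) and the imprinted noncoding RNA H19 (15.9-fold). Among the largest falls were SCRT1, a neural transcriptional repressor (6.01 ± 0.37 to 0.662 ± 0.071 CPM), TRIM67 (10.5 ± 0.38 to 0.965 ± 0.15 CPM), PKIB, a protein kinase A inhibitor (39.9 ± 2.1 to 4.94 ± 0.46 CPM), and NRSN1 (7.07 ± 0.29 to 0.921 ± 0.22 CPM). The readthrough gene RAB4B-EGLN2, whose reads overlap those of its 2 component genes, is listed at 6.33 ± 1.8 CPM in control and 0.0451 ± 0.039 CPM in ATG7 KO. Its edgeR call was lost when any 1 of the 6 libraries was left out, and the call of ABHD14A-ACY1 (5.38 ± 5.8 and 0.378 ± 0.26 CPM) was lost without any 1 of 5 of them.

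The innate immune lists rose in ATG7 KO. All 28 tested interferon-stimulated genes rose, with a median log2 change of 2.43 (camera adjusted p = 2.04e-19, and adjusted p = 0.00628 with an estimated correlation). IFI27 rose by 4.23 (SE 0.059), OAS2, a sensor of double-stranded RNA, by 3.80 (SE 0.065), and MX1, an antiviral GTPase, by 3.60 (SE 0.075). All 15 MHC class I and antigen presentation genes rose by a median of 0.84 (camera adjusted p = 4.05e-10, and adjusted p = 0.00628 with an estimated correlation). Among them were B2M (402 ± 1.8 to 722 ± 15 CPM), the peptide transporter TAP1 (51.2 ± 2.3 to 111 ± 1.9 CPM) and the trimming peptidase ERAP2 (87.2 ± 2.3 to 169 ± 2.7 CPM). Levels of HLA genes, such as HLA-C (170 ± 5.8 to 321 ± 2.7 CPM), are uncertain because near-identical paralogs can share reads. Of 23 NF-kB target genes 21 rose and 0 fell (median 1.04, camera adjusted p = 1.66e-07, and adjusted p = 0.00848 with an estimated correlation). They included the chemokine CCL2 (34.6 ± 1.7 to 91.1 ± 5.7 CPM), the adhesion molecule ICAM1 (32.9 ± 2.2 to 90.1 ± 4.1 CPM) and TNFAIP2 (56.1 ± 1.9 to 219 ± 10 CPM). Blood cell markers, a list kept to watch for other cells, lay at low levels in the same libraries. Of 5 tested, 3 rose and 1 fell (camera adjusted p = 0.378), with PTPRC at 0.174 ± 0.11 and 1.47 ± 0.067 CPM and CD68 at 2.27 ± 0.36 and 5.73 ± 0.54 CPM in control and ATG7 KO.

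Cell identity genes moved in opposite directions. Of 21 tested neuroendocrine markers 18 fell and 2 rose (median −1.54, camera adjusted p = 1.96e-06, and adjusted p = 0.0187 with an estimated correlation). NCAM1, a neural adhesion molecule, fell by 2.55 on the log2 scale (SE 0.073), the transcription factor INSM1 fell by 1.54 (SE 0.045), and the secretory granule protein CHGB fell by 1.82 (SE 0.057). Of 20 non-neuroendocrine markers 19 rose and 0 fell (median 0.99, camera adjusted p = 1.97e-10, and adjusted p = 0.0187 with an estimated correlation). They included ANXA1 (50.1 ± 1.4 to 147 ± 1.8 CPM) and the receptor tyrosine kinase AXL (17.9 ± 0.91 to 55.0 ± 3.9 CPM). Of 24 YAP/TAZ target genes 15 rose and 6 fell (16 rose when adjusted over the list alone). Their median was 0.59 (camera adjusted p = 0.00265, and adjusted p = 0.0476 with an estimated correlation). CPA4 rose by 2.94 (SE 0.061) and CCN1 by 1.37 (SE 0.05), while AMOTL1 fell by 1.47 (SE 0.04). The list shares AXL and MYOF with the non-neuroendocrine markers. Of 25 epithelial-mesenchymal transition genes 13 rose and 5 fell (median 0.35, camera adjusted p = 0.00785, but adjusted p = 0.322 with an estimated correlation). This list mixes epithelial genes, such as CDH1, EPCAM and KRT8, with mesenchymal ones, such as VIM, FN1 and CDH2. Its counts, median and camera test therefore give no direction of a transition in any of the comparisons. FN1, fibronectin, rose from 137 ± 6.6 to 398 ± 16 CPM, whereas CDH2, N-cadherin, fell from 54.5 ± 0.62 to 13.5 ± 0.89 CPM. Fibroblast markers, a second list kept to watch for other cells, rose beside these genes in 7 of 11 cases with 0 falls (camera adjusted p = 6.71e-05, but adjusted p = 0.0782 with an estimated correlation). COL3A1 went from 75.1 ± 1.5 to 327 ± 7 CPM and COL1A1, which both lists contain, from 19.7 ± 1 to 99.1 ± 6.8 CPM, while PDGFRA stood at 2.29 ± 0.4 and 2.23 ± 0.14 CPM. Of the keratinocyte and airway markers TP63 alone was tested, and it rose from 3.14 ± 0.2 to 9.13 ± 0.25 CPM. Of 21 Notch pathway genes 7 rose and 11 fell (median −0.28, camera adjusted p = 0.26). HES6 fell from 74.7 ± 3.8 to 24.1 ± 1.2 CPM and HES1 rose from 10.8 ± 1.5 to 22.4 ± 0.73 CPM.

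Genes of protein turnover and stress mostly moved by less than 2-fold in ATG7 KO. Of 34 NRF2 target genes, the antioxidant programme that p62 can release through KEAP1, 22 rose and 4 fell (median 0.25, camera adjusted p = 0.000491, but adjusted p = 0.076 with an estimated correlation). NQO1 rose from 265 ± 3 to 523 ± 12 CPM and the efflux pump ABCC3 from 10.9 ± 1.3 to 37.4 ± 1.2 CPM. Of 31 proteasome subunits 26 rose and 2 fell (median 0.28, camera adjusted p = 9.04e-07, but adjusted p = 0.0863 with an estimated correlation). PSMD12 rose by 0.49 (SE 0.036). Of 27 lysosome genes 19 rose and 3 fell (18 and 5 with library totals in place of TMM; median 0.35, camera adjusted p = 0.000211, but adjusted p = 0.0921 with an estimated correlation). CTSD rose by 0.52 (SE 0.033). The core autophagy machinery split, 13 of 29 rising and 9 falling (10 falling when adjusted over the list alone), with a camera adjusted p of 0.549. WIPI1 fell from 21.2 ± 0.29 to 10.4 ± 0.98 CPM and ATG3 rose from 86.2 ± 3.1 to 115 ± 0.46 CPM. The direction of this list's small median, 0.03, depended on the scaling of the libraries. Of 15 autophagy receptors other than SQSTM1, 8 rose and 5 fell (camera adjusted p = 0.238), with CALCOCO2 up by 0.52 (SE 0.039). ER chaperones and unfolded protein response genes rose in 12 of 20 cases and fell in 1 (camera adjusted p = 0.00154, but adjusted p = 0.308 with an estimated correlation). Cytosolic heat shock genes rose in 12 of 15 and fell in 1 (11 and 2 with library totals in place of TMM, camera adjusted p = 0.00377, but adjusted p = 0.306 with an estimated correlation). Of 32 ATF4 target genes 19 fell and 5 rose (median −0.20, camera adjusted p = 0.0148, but adjusted p = 0.15 with an estimated correlation). ASNS, asparagine synthetase, fell from 217 ± 5 to 135 ± 1.9 CPM, whereas WARS1, a tryptophanyl-tRNA synthetase that interferon also induces, rose from 119 ± 1.9 to 243 ± 6.7 CPM.

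Metabolic and growth lists completed the comparison. Of 24 cholesterol synthesis genes 17 rose and 2 fell (camera adjusted p = 0.000161, and adjusted p = 0.0215 with an estimated correlation). Of 22 ribosome biogenesis genes 18 rose and 0 fell (18 and 2 with library totals in place of TMM, camera adjusted p = 2.89e-05, and adjusted p = 0.0476 with an estimated correlation). NIP7 rose by 0.55 (SE 0.041). Cytosolic ribosomal protein genes, which have many processed pseudogenes and are therefore uncertain, fell in 20 of 38 cases and rose in 7 (26 and 3 with library totals in place of TMM; camera adjusted p = 0.0135, but adjusted p = 0.5 with an estimated correlation). G2/M genes rose in 22 of 27 cases and fell in 1 (23 rising when adjusted over the list alone, 19 and 2 with library totals in place of TMM; camera adjusted p = 1.51e-05, but adjusted p = 0.0921 with an estimated correlation). CCNB1 rose by 0.47 (SE 0.03). G1/S and DNA replication genes rose in 20 of 28 cases and fell in 3 (14 and 3 with library totals in place of TMM, camera adjusted p = 0.000794, but adjusted p = 0.124 with an estimated correlation). RRM2 rose by 0.60 (SE 0.028). Nuclear-encoded oxidative phosphorylation genes rose in 19 of 30 cases and fell in 2 (camera adjusted p = 0.00224, but adjusted p = 0.325 with an estimated correlation). For this list 20 rose when adjusted over the list alone. With relative log expression size factors 21 rose and 1 fell, and with library totals in place of TMM 13 rose and 3 fell. Of 13 mitochondrially encoded genes 1 rose (camera adjusted p = 0.802), MT-ND3, by 0.38 (SE 0.069). Lists without a camera call were hypoxia and glycolysis (6 of 23 rose and 8 fell, adjusted p = 0.507; PDK1 fell by 1.05), p53 targets (8 of 22 rose and 8 fell, adjusted p = 0.911; CDKN1A fell by 0.91), the BCL2 family (5 of 15 rose and 4 fell, adjusted p = 0.957; BAX rose by 0.68, HRK fell by 1.63) and drug efflux and platinum transport (6 of 14 rose and 4 fell, adjusted p = 0.378). With library totals in place of TMM the BCL2 family counts became 4 and 6, and those of hypoxia and glycolysis genes 3 and 10. The camera test also gave no call for immediate early genes (9 of 18 rose and 3 fell, adjusted p = 0.238; JUN fell by 0.80) or for replication-dependent histone genes, which have near-identical copies (1 of 8 rose, adjusted p = 0.404). The labels do not say whether the knockout cells were clones or pools, so all ATG7 KO libraries may come from 1 derived population.

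**Figure D2:**
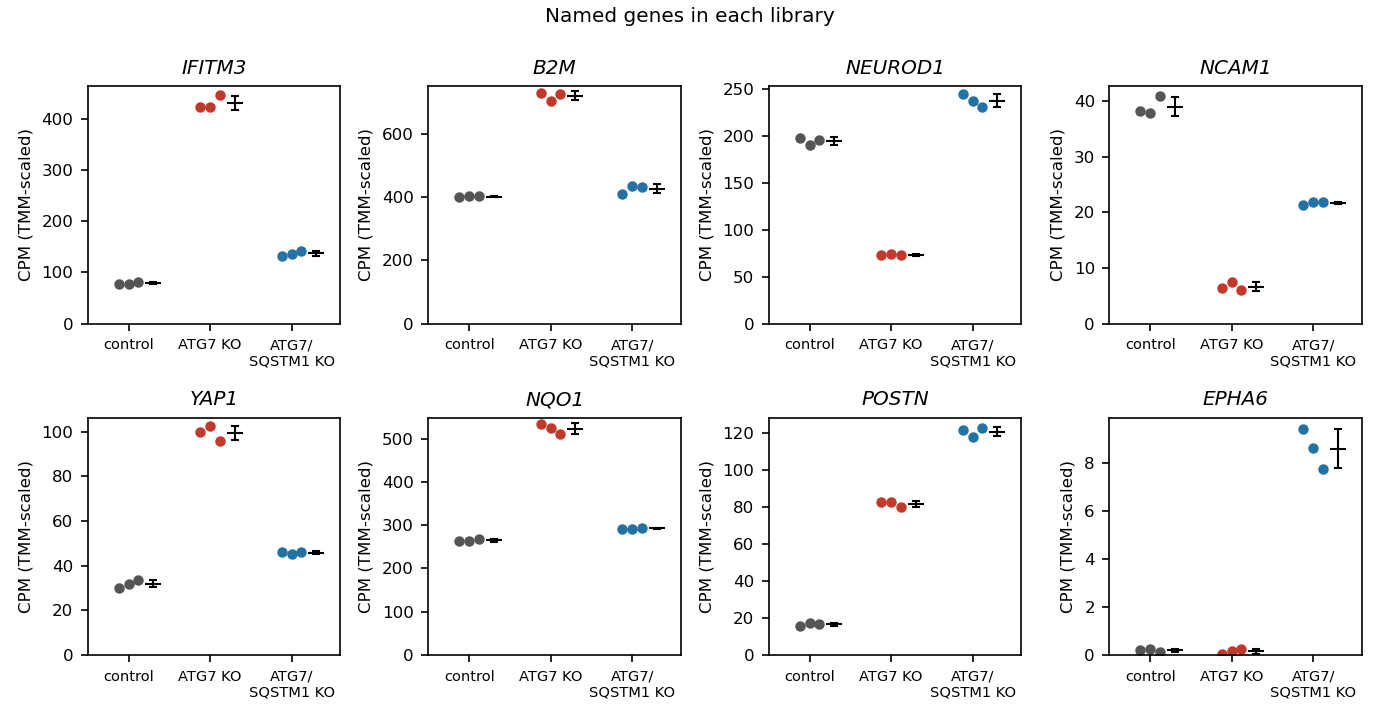
CPM (vertical axes) of IFITM3, B2M, NEUROD1, NCAM1, YAP1, NQO1, POSTN and EPHA6 in each of the 9 libraries; points are libraries, bars the mean ± SD of the 3 libraries of a group. IFITM3, B2M, YAP1 and NQO1 were highest in ATG7 KO, NEUROD1 and NCAM1 lowest there, and POSTN (120.5 CPM) and EPHA6 (8.58 CPM) highest in ATG7/SQSTM1 KO.

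The second comparison set the ATG7/SQSTM1 KO cells against control and asks what differs when both genes are lost. Of 28 interferon-stimulated genes 17 were higher than in control and 2 lower, and of 31 proteasome subunits 24 were lower and 3 higher. With an estimated correlation camera called neither list (adjusted p = 0.116 and adjusted p = 0.219), and neuroendocrine markers were not called as a group. IFITM3 stood at 137 ± 4.8 CPM against 78.3 ± 1.9 CPM, and the proteasome ATPase PSMC1 at 112 ± 3 CPM against 155 ± 7.7 CPM. The largest rises included genes that were near their control level in ATG7 KO: EPHA6, an ephrin receptor (0.194 ± 0.059 to 8.58 ± 0.82 CPM, 43.4-fold), CKM, muscle creatine kinase (0.262 ± 0.099 to 6.63 ± 0.3 CPM), and DMD, dystrophin (0.972 ± 0.19 to 12.9 ± 0.22 CPM). STEAP4 (12.8-fold), AQP1 (0.817 ± 0.31 to 7.46 ± 0.65 CPM) and CPA4 (8.42-fold) were among the largest rises here too. Among the largest falls were IDO1, which breaks down tryptophan (5.11 ± 0.2 to 0.373 ± 0.13 CPM), IGF2BP1, an mRNA-binding protein (46.4 ± 1.3 to 7.81 ± 0.074 CPM), the peptidase ANPEP (5.65 ± 0.042 to 0.925 ± 0.3 CPM) and the noncoding RNA FENDRR (6.39 ± 0.76 to 1.08 ± 0.057 CPM). Across all tested genes edgeR called 7281 changed (38.6%), 3580 higher and 3701 lower, of which 414 were at least 2-fold higher and 312 at least 2-fold lower. The readthrough gene BIVM-ERCC5 (8.42 ± 0.97 and 0.0645 ± 0.084 CPM) lost its edgeR call without any 1 of the 6 libraries, and its reads overlap those of BIVM and ERCC5.

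Of the lists, 12 passed camera's threshold with the preset correlation and 0 with an estimated correlation, where the lowest adjusted p was 0.116. Among interferon-stimulated genes 17 of 28 rose and 2 fell (19 rising when adjusted over the list alone; median 0.31, camera adjusted p = 5.29e-05, but adjusted p = 0.116 with an estimated correlation). IFIT2 rose from 5.87 ± 0.25 to 11.8 ± 0.46 CPM. Of 31 proteasome subunits 24 fell and 3 rose (4 rising when adjusted over the list alone; median −0.18, camera adjusted p = 3.71e-05, but adjusted p = 0.219 with an estimated correlation). PSMC2 fell by 0.48 (SE 0.037). Immediate early genes rose in 9 of 18 cases with 0 falls (camera adjusted p = 0.000145, but adjusted p = 0.219 with an estimated correlation). Among them were FOS (2.04 ± 0.18 to 5.52 ± 1.3 CPM) and MYC (1167 ± 7.9 to 1625 ± 32 CPM). Of 22 ribosome biogenesis genes, a list that also holds MYC, 15 fell and 5 rose (camera adjusted p = 0.0131, but adjusted p = 0.259 with an estimated correlation). NPM1 went from 3675 ± 62 to 2973 ± 32 CPM. Hypoxia and glycolysis genes rose in 13 of 23 cases and fell in 1 (camera adjusted p = 0.00153, but adjusted p = 0.611 with an estimated correlation). P4HA1 rose by 0.49 (SE 0.04). YAP/TAZ targets rose in 14 of 24 cases and fell in 5 (camera adjusted p = 0.00411, but adjusted p = 0.116 with an estimated correlation). CCN1 reached 54.2 ± 2.3 CPM from 17.4 ± 0.74 CPM. Cholesterol synthesis genes rose in 15 of 24 cases and fell in 3 (camera adjusted p = 0.00442, but adjusted p = 0.116 with an estimated correlation). Epithelial-mesenchymal transition genes rose in 13 of 25 cases and fell in 5 (14 rising when adjusted over the list alone; camera adjusted p = 0.00467, but adjusted p = 0.483 with an estimated correlation). FN1 fell from 137 ± 6.6 to 70.7 ± 1.1 CPM.

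Beside these, fibroblast markers rose in 7 of 11 cases and fell in 2 (camera adjusted p = 0.00442, but adjusted p = 0.259 with an estimated correlation). POSTN stood at 16.6 ± 0.87 and 120.5 ± 2.3 CPM and COL6A3 lower, at 16.3 ± 1.9 and 11.8 ± 0.84 CPM. Ribosomal protein genes rose in 19 of 38 cases and fell in 3 (camera adjusted p = 0.00679, but adjusted p = 0.611 with an estimated correlation). Histone genes fell in 6 of 8 cases (camera adjusted p = 0.00915, but adjusted p = 0.169 with an estimated correlation). H1-2 stood at 10.5 ± 1 and 6.71 ± 0.71 CPM. G2/M genes fell in 14 of 27 cases and rose in 5 (16 falling when adjusted over the list alone), with a camera adjusted p of 0.0472, but adjusted p = 0.61 with an estimated correlation. In the list G2/M genes, ATG7/SQSTM1 KO vs control, the camera adjusted p was 0.0509 without control replicate 1, 0.0592 without control replicate 2, 0.0977 without ATG7/SQSTM1 KO replicate 1, 0.0573 without ATG7/SQSTM1 KO replicate 3, and 0.0509 with relative log expression size factors. Lists that gave no camera call included NRF2 targets (11 of 34 rose and 17 fell, 12 and 18 when adjusted over the list alone, adjusted p = 0.259) and neuroendocrine markers (7 of 21 rose and 6 fell, adjusted p = 0.969). The NRF2 target HMOX1, heme oxygenase 1, rose from 39.5 ± 0.65 to 58.9 ± 1.1 CPM, while the cystine transporter gene SLC7A11 fell from 50.1 ± 4.2 to 30.2 ± 1.1 CPM. NEUROD1 was at 237 ± 6.8 CPM, above control, and NCAM1 at 21.7 ± 0.24 CPM, below it. Non-neuroendocrine markers (11 of 20 rose and 7 fell, 8 falling when adjusted over the list alone, camera adjusted p = 0.428) held both YAP1, up by 0.53 (SE 0.043), and PLAU, urokinase, which fell by 1.61 (SE 0.073). NF-kB targets (6 of 23 rose and 9 fell, camera adjusted p = 0.94) and MHC class I genes (2 of 15 rose and 7 fell, 3 rising when adjusted over the list alone, camera adjusted p = 0.428) were also not called. In the list G1/S and DNA replication genes, ATG7/SQSTM1 KO vs control, 3 of 28 rose and 11 fell with a camera adjusted p of 0.0682, which was 0.0381 without ATG7/SQSTM1 KO replicate 2. Among ER chaperones 6 of 20 rose and 4 fell (camera adjusted p = 0.515), HERPUD1 going from 48.9 ± 1.7 to 106 ± 5.2 CPM.

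The third comparison set ATG7/SQSTM1 KO against ATG7 KO and asks what differs between cells that lack both genes and cells that lack ATG7 alone. The labels do not say whether the double knockout was made from the same ATG7 KO cells. Interferon, antigen presentation and NF-kB genes were lower, NRF2 targets were lower, neuroendocrine genes were higher and non-neuroendocrine genes were lower. OAS3 was at 202 ± 4.6 CPM in ATG7 KO and 39.7 ± 1.6 CPM in ATG7/SQSTM1 KO, NQO1 at 523 ± 12 and 293 ± 1.1 CPM, and NEUROD1 at 73.3 ± 0.93 and 237 ± 6.8 CPM. The largest falls included TRIM22, an interferon-induced ubiquitin ligase (14.3 ± 0.63 to 0.594 ± 0.089 CPM, 24.0-fold), MX2 (34.5 ± 1.6 to 2.46 ± 0.12 CPM), FABP7, a fatty acid binding protein (147 ± 2.8 to 11.1 ± 0.47 CPM), and the MHC class II gene HLA-DRA (21.8 ± 0.51 to 2.13 ± 0.4 CPM). The largest rises included NCAN, neurocan (22.6-fold), CSMD3 (20.3-fold), the axon guidance gene SLIT1 (17.0-fold) and GUCY1A2 (21.5-fold). In all, edgeR called 11395 genes changed (60.5%), 5753 higher and 5642 lower, of which 1710 were at least 2-fold higher and 727 at least 2-fold lower.

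Of the lists, 18 passed camera's threshold with the preset correlation and 6 did so with an estimated correlation. All 28 interferon-stimulated genes fell (median −2.20, camera adjusted p = 3.3e-16, and adjusted p = 0.00854 with an estimated correlation). All 15 MHC class I genes fell (median −0.89, camera adjusted p = 2.26e-09, and adjusted p = 0.00854 with an estimated correlation). Of 23 NF-kB targets 19 fell and 0 rose (median −0.67, camera adjusted p = 8.54e-07, and adjusted p = 0.0117 with an estimated correlation). Of 34 NRF2 targets 28 fell and 3 rose (median −0.29, camera adjusted p = 1.04e-06, and adjusted p = 0.0272 with an estimated correlation). GCLC, the catalytic subunit for glutathione synthesis, went from 109 ± 1.2 to 65.5 ± 0.69 CPM and ME1 from 232 ± 3.7 to 140.2 ± 6.6 CPM, whereas HMOX1 rose from 25.8 ± 2 to 58.9 ± 1.1 CPM. Of 21 neuroendocrine markers 18 rose and 2 fell (median 1.45, camera adjusted p = 2.17e-06, and adjusted p = 0.0218 with an estimated correlation). SYP, synaptophysin, rose from 23.5 ± 1.6 to 64.3 ± 3.3 CPM. Of 20 non-neuroendocrine markers 19 fell and 0 rose (median −0.84, camera adjusted p = 4.33e-09, and adjusted p = 0.0272 with an estimated correlation). PLAU fell from 62.5 ± 2.8 to 6.91 ± 0.63 CPM. Blood cell markers fell in 3 of 5 cases in the same libraries (camera adjusted p = 0.395), CD68 by 1.85 (SE 0.18). Fibroblast markers fell in 6 of 11 cases and rose in 3 (camera adjusted p = 0.168), COL1A1 going from 99.1 ± 6.8 to 35.0 ± 1.7 CPM and POSTN from 81.5 ± 1.6 to 120.5 ± 2.3 CPM.

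The other camera calls in this comparison were lost with an estimated correlation. Proteasome subunits fell in 28 of 31 cases (camera adjusted p = 1.12e-09, but adjusted p = 0.0505 with an estimated correlation). Lysosome genes fell in 22 of 27 with 4 rising (camera adjusted p = 5.01e-05, but adjusted p = 0.0933 with an estimated correlation). PSMC1 fell by 0.92 (SE 0.036) and CTSD by 0.73 (SE 0.033). G2/M genes fell in 22 of 27 cases and rose in 1 (2 rising when adjusted over the list alone, 21 and 4 with library totals in place of TMM; camera adjusted p = 5.88e-06, but adjusted p = 0.0961 with an estimated correlation). G1/S genes fell in 19 of 28 and rose in 4 (5 rising when adjusted over the list alone, 7 with library totals in place of TMM; camera adjusted p = 0.000869, but adjusted p = 0.134 with an estimated correlation). Ribosome biogenesis genes fell in 18 of 22 cases and rose in 3 (camera adjusted p = 2.03e-05, but adjusted p = 0.0505 with an estimated correlation). Ribosomal protein genes rose in 32 of 38 and fell in 1 (2 falling when adjusted over the list alone, and also with relative log expression size factors; camera adjusted p = 2.27e-05, but adjusted p = 0.299 with an estimated correlation). Heat shock genes fell in 12 of 15 cases and rose in 2 (camera adjusted p = 0.00292, but adjusted p = 0.274 with an estimated correlation). ER chaperones fell in 13 of 20 and rose in 1 (13 and 2 with library totals in place of TMM, camera adjusted p = 0.013, but adjusted p = 0.433 with an estimated correlation). Histone genes fell in 6 of 8 (camera adjusted p = 0.0166, but adjusted p = 0.0961 with an estimated correlation). Hypoxia and glycolysis genes rose in 13 of 23 cases and fell in 2 (camera adjusted p = 0.0206, but adjusted p = 0.601 with an estimated correlation). ENO2 rose from 20.9 ± 1.6 to 59.7 ± 3.5 CPM. Cholesterol synthesis genes fell in 13 of 24 cases and rose in 5 (camera adjusted p = 0.0284, but adjusted p = 0.097 with an estimated correlation). For oxidative phosphorylation, 16 of 30 fell and 3 rose (17 falling when adjusted over the list alone; camera adjusted p = 0.0169, 0.0528 with library totals in place of TMM, and adjusted p = 0.47 with an estimated correlation). ATF4 targets rose in 18 of 32 cases and fell in 6 (camera adjusted p = 0.0547, below the threshold at 0.0499 with the replicate number as a block and at 0.0444 with library totals in place of TMM, but adjusted p = 0.258 with an estimated correlation). In the list epithelial-mesenchymal transition genes, ATG7/SQSTM1 KO vs ATG7 KO, 5 of 25 rose and 12 fell (6 rising when adjusted over the list alone), with a camera adjusted p of 0.11 that was 0.0397 without ATG7/SQSTM1 KO replicate 3. YAP/TAZ targets rose in 10 of 24 cases and fell in 10 (camera adjusted p = 0.997).

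**Figure D3:**
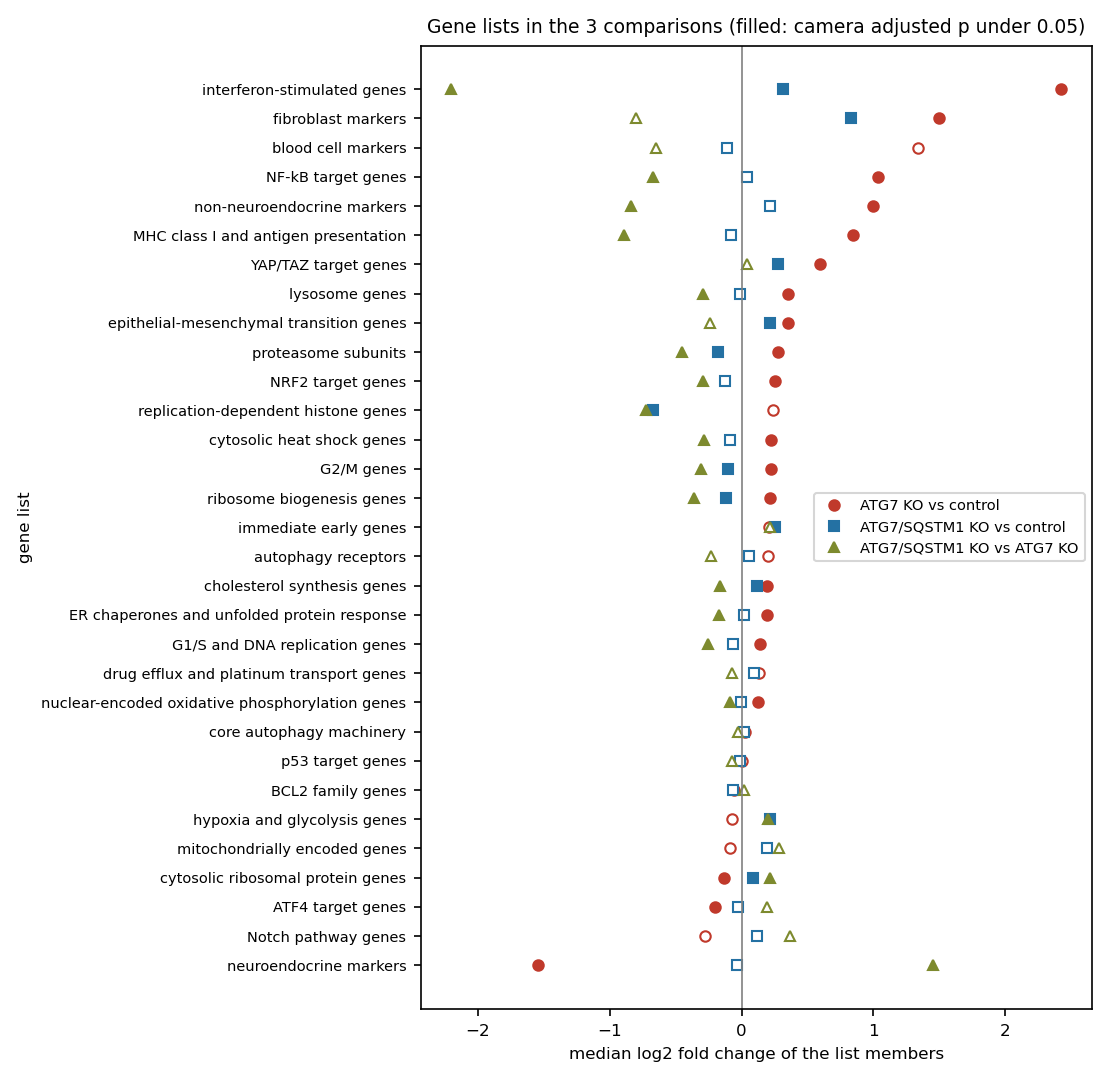
Median log2 change of the members of each of 31 gene lists (horizontal axis) in the 3 comparisons; filled symbols have a camera adjusted p under 0.05 with the preset correlation. Interferon-stimulated genes lay at 2.43, 0.31 and −2.20 and neuroendocrine markers at −1.54, −0.04 and 1.45 for ATG7 KO against control, ATG7/SQSTM1 KO against control and ATG7/SQSTM1 KO against ATG7 KO.

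The last comparison followed the genes changed in ATG7 KO into the ATG7/SQSTM1 KO cells, and asks how many of the changes seen without ATG7 are opposite in direction between the cells lacking ATG7 alone and those lacking both genes. All 28 interferon-stimulated genes that rose in ATG7 KO were lower again in ATG7/SQSTM1 KO, and 9 of them no longer differed detectably from control. Of the 18 neuroendocrine markers that fell, 17 were higher again, 7 of them not detectably different from control, and all 19 non-neuroendocrine markers that rose were lower again, 1 of them not detectably different from control. Chosen after their values were seen, 4 genes show the range. HES6 fell and came back, at 74.7 ± 3.8, 24.1 ± 1.2 and 79.8 ± 7.4 CPM in control, ATG7 KO and ATG7/SQSTM1 KO, and ERAP2 rose and came back, at 87.2 ± 2.3, 169 ± 2.7 and 88.3 ± 0.62 CPM. HRK did not come back (6.70 ± 0.56, 2.16 ± 0.17 and 2.50 ± 0.16 CPM), and CPA4 also stayed near its ATG7 KO level (5.33 ± 0.035, 40.8 ± 2.2 and 44.9 ± 1.2 CPM). Of the 10688 genes changed in ATG7 KO, 8264 (77.3%) changed in the opposite direction between ATG7 KO and ATG7/SQSTM1 KO, 4146 that had risen and 4118 that had fallen. A further 418 changed again in the same direction and 2006 were not called between both knockouts. Of the genes that turned, 4703 were not detectably different from control in ATG7/SQSTM1 KO, 2178 had passed beyond the control level and 1383 lay between. Of the 795 genes at least 2-fold higher in ATG7 KO, 652 (82%) were lower again, and of the 1561 at least 2-fold lower, 1329 (85.1%) were higher again.

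Both comparisons use the ATG7 KO libraries, so chance values in those libraries push the counts the same way. In 20 simulated draws in which ATG7/SQSTM1 KO had the ATG7 KO means, the median count of genes that turned was 1 and the highest 3, and with no group different at all it was 0 with a highest of 1. Independent lists of these sizes would share 1601 genes that rose and then fell and 1630 that fell and then rose. Across genes, which are not independent replicates, the log2 changes of both comparisons correlated at r = −0.748 (simulated with no effect −0.503), with a covariance of −0.462 (simulated −0.04). The control libraries are shared as well when each knockout is set against control. There 1579 genes were higher in both knockouts (independent lists would share 1016), 1449 were lower in both (1049) and 2178 went opposite ways (2065). The correlation across genes was 0.283 where simulated unchanged groups gave 0.493, and the covariance was 0.121 against a simulated 0.04. The simulated unchanged groups gave a median of 0 genes and a highest of 1 both for genes higher in both knockouts and for genes lower in both. With 3 control libraries a split into parts of 2 or more is not possible, and what the shared controls add beside real changes was not measured.

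**Figure D4:**
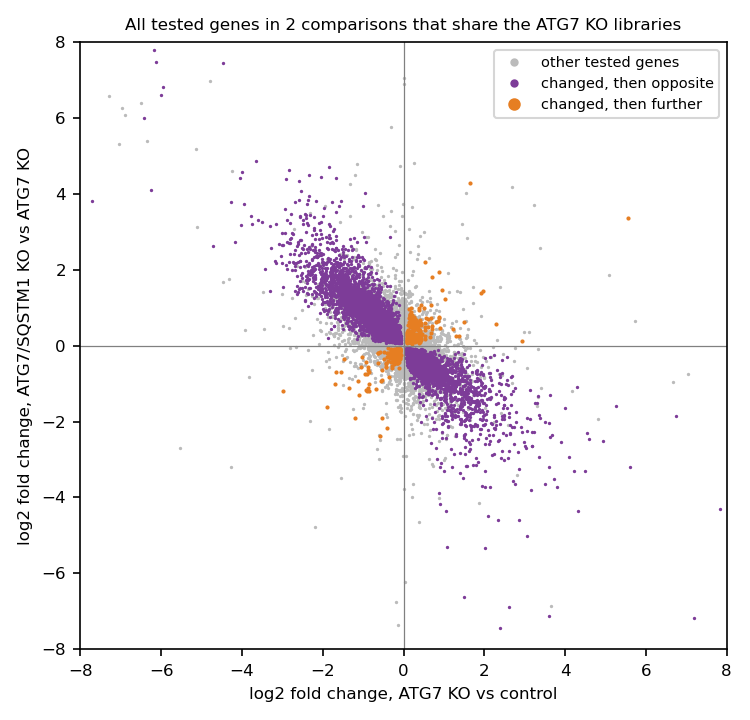
Log2 change of each tested gene in ATG7 KO against control (horizontal axis) and in ATG7/SQSTM1 KO against ATG7 KO (vertical axis), which share the ATG7 KO libraries; purple points are the 8264 genes called in both in opposite directions and orange points the 418 called in the same direction. The cloud runs from upper left to lower right, and 5 genes lie outside the axes of ±8.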

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

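No result turned its direction as a called result. With a 1.5-fold null in place of any change, the counts of changed genes went from 10688 to 2415 (ATG7 KO against control), from 7281 to 564 (ATG7/SQSTM1 KO against control) and from 11395 to 2628 (ATG7/SQSTM1 KO against ATG7 KO), since the null asks for a larger change. With an estimated inter-gene correlation fewer lists passed camera's threshold. They went from 20 to 8, from 12 to 0 and from 18 to 6 in the same order. Higher correlation cannot be the cause for every list, since some estimates lay below the preset 0.01. For MHC class I genes the estimate was −0.006. Their camera adjusted p in ATG7 KO against control still rose from 4.05e-10 to 0.00628. For histone genes the estimate was −0.043, and the camera adjusted p in ATG7/SQSTM1 KO against ATG7 KO rose from 0.0166 to 0.0961. With an estimated correlation camera also takes the 6 residual degrees of freedom for its test. With the preset correlation it takes a far larger number, set by the count of tested genes. The p-values of both settings therefore differ in more than the correlation. How much of the loss of calls each part gave was not measured. For targeted gene SQSTM1, ATG7 KO vs control, the log2 change was 0.07 with DESeq2 (adjusted p = 0.0368) against 0.05. For targeted gene ATG7, ATG7/SQSTM1 KO vs ATG7 KO, it ran from −0.24 without ATG7 KO replicate 2 (edgeR adjusted p = 0.0127) to −0.06 without ATG7 KO replicate 3, against −0.14, and the cause was not tested. Leaving out 1 library at a time gave 9939 to 10182, 6361 to 6538 and 10748 to 10819 changed genes, 7697 to 7983 genes that went back, and 20 to 20, 11 to 13 and 18 to 19 lists. The other settings kept the counts of changed genes, of genes that went back and of lists past camera's threshold within 1.5 times, while counts of members within a list moved more in some cases when the scaling factors were replaced. Library totals alone also moved the split of higher and lower genes, to 4676 and 5948 from 5348 and 5340 (ATG7 KO against control), to 3494 and 3784 from 3580 and 3701 (ATG7/SQSTM1 KO against control) and to 6273 and 5138 from 5753 and 5642 (ATG7/SQSTM1 KO against ATG7 KO). Same-numbered libraries did not deviate together (r from −0.172 to 0.134 over 9 pairs, and 3 of 9 libraries correlated best with their own number), so the numbers were not taken to pair the libraries. With the replicate number as a block the counts were 10564, 7137 and 11262 genes, 8165 that went back, and 20, 12 and 19 lists, the gained one being ATF4 target genes, ATG7/SQSTM1 KO vs ATG7 KO (camera adjusted p = 0.0499 against 0.0547). Over list tests, 552 of the leave-one-out results kept their side of the threshold, 4 lost it and 2 gained it, and over named genes 2396 kept it, 48 lost it and 4 gained it. In simulated counts for ATG7 KO against control (18530 genes), 27 of 50 genes changed 1.5-fold were recovered, and the part that depth or replicate number has in this was not tested.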

Other observations

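The gene groups in this paragraph and the next were put together after the values were seen, so their counts describe and do not test. In ATG7 KO 10 of 11 MHC class II genes rose against control and 0 fell, and in ATG7/SQSTM1 KO 10 of 11 were lower than in ATG7 KO. CD74, the invariant chain, stood at 32.2 ± 0.35, 91.3 ± 3.9 and 23.2 ± 1.2 CPM in control, ATG7 KO and ATG7/SQSTM1 KO, and CIITA, the transactivator of the class, at 6.82 ± 0.95, 13.5 ± 0.92 and 8.53 ± 0.97 CPM. Blood cells that present antigen carry this class too, and the blood cell markers PTPRC (0.174 ± 0.11, 1.47 ± 0.066 and 0.386 ± 0.096 CPM), CD68 (2.27 ± 0.36, 5.73 ± 0.54 and 1.58 ± 0.38 CPM) and CD14 (0.406 ± 0.13, 1.45 ± 0.34 and 0.922 ± 0.12 CPM) moved the same way. Whether such cells account for the class II genes was not tested. Of 14 nucleic acid sensors and related genes 12 rose in ATG7 KO (11 with library totals), and 12 were lower in ATG7/SQSTM1 KO than in ATG7 KO, 11 of them among those that rose (IRF3 rose and was not lower, TREX1 was lower without a rise). The related genes, among them IRF1, IRF3, MAVS, TREX1, SAMHD1 and ADAR, are not sensors themselves. DDX58 and IFIH1 are also in the interferon-stimulated list, so the counts are not a separate observation for them. Whether the other members moved apart from the interferon-stimulated genes was not tested either. Examples are the RNA sensor DDX58 at 8.87 ± 0.77, 45.7 ± 2.6 and 8.19 ± 1.6 CPM and the DNA sensor IFI16 at 37.0 ± 2.5, 116 ± 2.3 and 19.1 ± 2.2 CPM. Interferon transcripts were too few to be tested: summed over the 3 libraries of a group, the counts were 2, 30 and 32 for IFNL1, 2, 10 and 7 for IFNB1, and 5, 42 and 19 for IFNE. They were 4, 0 and 2 for IFNG and 2, 0 and 0 for IFNL3, and IFNA1, IFNA2, IFNK and IFNL2 had at most 1 count in any group.

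Of 25 synaptic vesicle release genes 22 fell in ATG7 KO and 1, SYT1, rose. In ATG7/SQSTM1 KO 19 were higher than in ATG7 KO and 2 lower. SYP, SYT1 and SNAP25 are also in the neuroendocrine list, so the counts are not a separate observation for them. CPLX2 stood at 25.1 ± 2, 3.72 ± 0.24 and 29.4 ± 1.3 CPM and UNC13A at 33.1 ± 2.2, 8.12 ± 0.4 and 24.9 ± 1.9 CPM in control, ATG7 KO and ATG7/SQSTM1 KO. Of 18 translation factors and related genes 14 fell in ATG7 KO and 2 rose (13 and 3 with relative log expression size factors), and 15 were higher in ATG7/SQSTM1 KO than in ATG7 KO, the 14 that fell and EEF1B2. EEF2 stood at 4443 ± 45, 3023 ± 34 and 4198 ± 120 CPM. Of 11 skeletal muscle genes 8 were higher in ATG7/SQSTM1 KO than in control and 0 lower. MYOD1 stood at 1.02 ± 0.38, 0.463 ± 0.14 and 2.45 ± 0.051 CPM and MYOG at 1.10 ± 0.13, 0.621 ± 0.096 and 2.32 ± 0.17 CPM.

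Of the tests below, those of GC content and length had their predictions written before the result was seen, and all others (splits, shared libraries, derivation, scaling, blood cells and both fibroblast tests) after it. Other splits of the 6 libraries compared were counted first. For genes changed, ATG7 KO vs control, 1 of 10 splits, the true one, gave as many genes and the highest other gave 0. For genes changed, ATG7/SQSTM1 KO vs control, it was 1 of 10 with a highest other of 1, and for genes changed, ATG7/SQSTM1 KO vs ATG7 KO, 1 of 10 with a highest other of 1. With 10 splits a share under 0.05 cannot be reached, so these counts cannot tell.

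For the genes changed in ATG7 KO that go back, 1 of 100 drawn splits of the 9 libraries, the true one, gave as many. The highest other count, 6738, came from the 1 drawn split that keeps the ATG7 KO libraries together as the ATG7 KO group. That split mixes control with ATG7/SQSTM1 KO libraries. Among the 98 others the highest was 385. Some of these may keep the ATG7 KO libraries together under the name of another group, which was not counted separately. Splits that part the ATG7 KO libraries put the differences between groups into the spread within them. Low counts were bound to follow there. The splits show that the ATG7 KO libraries stand apart from the others. They cannot tell whether the grouping of the others matters. With both knockouts simulated alike, the shared ATG7 KO libraries gave at most 3 such genes against 8264. In those draws no gene truly differed between both knockouts, whereas 11395 were called there in the data. A count near 0 was therefore to be expected. The draws cannot show what the shared libraries add beside real differences between both knockouts. The derivation of the ATG7 KO cells, apart from genotype, may be the cause. Of the changes, 44% went back to a level not detectably different from control. With no further ATG7 KO population the design cannot tell derivation from an effect of SQSTM1 loss.

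For the interferon-stimulated genes, higher in ATG7 KO and lower again in ATG7/SQSTM1 KO, library scaling cannot be the whole cause, since the smallest list median over 3 scalings and both comparisons was 2.16 on the log2 scale. Nor can a trend with GC content and gene length, since the smallest median was 2.22 after the trend was removed. Blood cells in the ATG7 KO cultures would bring their own transcripts, but the summed blood cell markers (6.03, 10.4 and 5.24 CPM) rose by 0.191% of the rise of the summed interferon-stimulated genes (702, 2970.3 and 864 CPM). Without the haemoglobin genes, which did not rise, the other 3 blood cell markers summed to 2.85, 8.65 and 2.89 CPM, a 3.04-fold rise in ATG7 KO that is 0.256% of the rise of the interferon-stimulated genes. A biological explanation, loss of ATG7 alone against loss of both genes, is open, and so is the derivation of the cells, since the labels do not say whether the double knockout was made from the same ATG7 KO cells.

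For the neuroendocrine and non-neuroendocrine genes, a trend with GC content and length cannot be the whole cause, since the smaller gap between the list medians was 2.33 on the log2 scale after its removal. Fibroblasts in the ATG7 KO cultures were first tested by asking for markers that spread widely and at least 1 that fell: the spread was 14.3 times the median standard error but 0 markers fell, so that test cannot tell. Fibroblasts as most of the RNA, if they lack neuroendocrine transcripts, would lower every neuroendocrine marker alike, but the spread of these was 7.16 times the median standard error, with 18 falling and 2 rising, so such dilution cannot be the whole cause. Fibroblasts beside a change in the cells themselves are left open. So is the derivation of the ATG7 KO cells: 36 members of both lists changed in ATG7 KO and went back, and no further ATG7 KO population is there to tell it from genotype.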
